A study of Homo sapiens with 6 samples.

How the data were processed

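MiRNA levels were measured in SCC9 and CAL27, established cell lines from human tongue squamous cell carcinoma. Each line was studied as a control and after stable transduction with shRNA1 or shRNA3, short hairpin RNAs against the long noncoding RNA NR_034085. All cultures received cisplatin at its IC50 for 24 h, and total RNA was taken with Trizol. That gave 6 groups with 1 array each, all on 1 slide. The labels do not say whether the control cells carried a vector, and no untreated cells were measured.

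The arrays were Agilent human miRNA arrays with 1 colour (Cy3), which hold 2549 human miRNAs with a median of 20 spots each. Per the file headers, Agilent Feature Extraction 11.0.1.1 read the scans. It subtracted background, combined spots into probes and probes into miRNAs, and flagged each miRNA as detected or not. The deposited scanner values are fluorescence intensity on a linear scale, with no normalization between arrays. The deposited series table holds log2 values that the authors had quantile normalized. Within each array its values ranked as total signal did (Spearman rho of 0.99988 on the SCC9 control and of 1 on the others). Its lowest value was 5 on the linear scale. The comparisons below start from the scanner values, and the series table served as an alternative. No array had a saturated spot (0 on each). The spike-in controls lay outside the manufacturer's range on all 6 arrays. Their hybridization signal (log10) was 1.39 on the SCC9 control against 1.96 with shRNA1 and 2.01 with shRNA3. In CAL27 it was 1.76 against 1.96 and 2.04. Their labelling signal was also lowest on the control array of each line. For arrays there is no read depth, and the number of arrays limits the precision.

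Total signal per miRNA was quantile normalized over all 2549 miRNAs, as the series description states for the study, floored at 3.85 and put on the log2 scale. The floor is the median over arrays of the lowest normalized signal of a detected miRNA. MiRNAs flagged as detected on at least 2 of 6 arrays were tested, which kept all 2549. Because the detection flag removed nothing, miRNAs over 4 times the median signal of the array on at least 2 arrays are called bright here (353), and the others dim. This limit was chosen after the data were seen.

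Models were fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a constant prior. P-values were adjusted by the Benjamini-Hochberg method over all 2549 miRNAs, and a miRNA was called at an adjusted p under 0.05. The overall knockdown contrast set 4 hairpin arrays against 2 controls with cell line as a term (3 residual degrees of freedom). A model with 1 mean for each line and arm (2 residual degrees of freedom) gave the knockdown within each line and the difference between the lines, always CAL27 minus SCC9. The cell line contrast set 3 CAL27 arrays against 3 SCC9 arrays with knockdown as a term. The hairpin contrast was shRNA3 minus shRNA1. No group had a repeat culture, so hairpins and lines stand in for replicates, and every p-value measures only the spread between these 6 arrays. Both hairpins of a line were compared with the same control array. Single hairpin arrays were also set against the control of their line with a limit of 2-fold and no test.

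Groups of miRNAs were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and fry beside it, adjusted over lists within a contrast. Of 28 lists, 25 had at least 3 members on the array. They cover miR-483, regulators of mitochondrial fission, let-7, miR-17-92 and paralogs, miR-200, squamous epithelium, p53 and DNA damage, the cisplatin response literature, oral carcinoma oncomiRs and suppressors, hypoxia, the miR-183 cluster, the miR-23-27-24 clusters, miR-221 and miR-222, miR-29, miR-15-16-195, the miR-99, miR-100 and miR-125 group, miR-320, NF-kB and inflammation, interferon and stress, markers of blood, fibroblasts and mesenchyme, endothelium, muscle, liver and neurons, embryonic and C19MC miRNAs, entries that are fragments of other RNAs, and GC-rich entries known for high background.

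The tests, lists, thresholds and the rule for naming miRNAs were set before the data were examined. For the knockdown the rule took both miR-483 arms and 10 miRNAs per direction: the largest changes that passed with the same sign on all 4 hairpin arrays, then, to fill the places, those with the largest smallest-of-4 difference. Within a line it took 5 per direction by the smaller difference of both hairpins. It took 4 per direction for the difference between lines, 12 for the cell line contrast among those that passed with no overlap between arrays, and 3 for the hairpins. From each list it took up to 4 members with the largest change.

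The code was tested on simulated data with independent noise of the size seen here and known changes in 200 miRNAs. At a true 2-fold change it called 92% of the changed miRNAs in the knockdown contrast, 84% in SCC9, 76% in CAL27, 70% for the difference between lines, 86% between the lines themselves and 82% between hairpins. These shares test the code and are not the sensitivity on the real arrays. For the knockdown contrast the simulation held no response that differed between the lines. In the real contrast miR-483-5p was 177-fold higher and did not pass. Alternatives set in advance covered other normalizations, floors, detection filters, background correction, miRNA summaries, priors, models and fold limits, each group left out in turn, each hairpin alone, and the deposited series table. Added after the data were seen were bright miRNAs alone, scaling on the 195 miRNAs that are bright on all 6 arrays, both together, each line alone, and the row of the slide as a block. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.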

Results

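MiRNA profiles of 6 arrays were compared, 1 each for control, shRNA1 and shRNA3 cells of the tongue squamous carcinoma lines SCC9 and CAL27, all after 24 h of cisplatin. The hairpins target NR_034085, a transcript of the long noncoding RNA gene ANXA2R-OT1 on chromosome 5 (43014729 to 43067439, GRCh38.p14), and the study asked which miRNAs change when it is silenced. The target itself has no probe on a miRNA array, so how far it was silenced was not analysed here. In the study's own account this RNA binds the precursor of miR-483 and miR-483-5p acts on the mitochondrial fission protein FIS1.

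The scanner software flagged nearly every miRNA as detected, 2544 of 2549 on the SCC9 control array and 2549 on each of the others. Total signal was 586831, 515949 and 560760 intensity units on the SCC9 control, shRNA1 and shRNA3 arrays, and 784442, 813013 and 948370 on the CAL27 ones. Most entries lay near a floor of nonspecific signal that differed between arrays. The median signal was 8.47 on the SCC9 control against 27.1 and 30.0 on the SCC9 hairpin arrays, and 18.0 on the CAL27 control against 27.9 and 31.3 on the CAL27 hairpin arrays. Control probes against fly miRNAs, which have no human target, moved with it: their median fold over the control of the line was 3.76 on SCC9 shRNA1, 4.25 on SCC9 shRNA3, 1.55 on CAL27 shRNA1 and 1.88 on CAL27 shRNA3. The spike-in signals were lowest on the control array of each line. Whether they are read from these same fly probes was not examined, so they do not count as a second measure. The shift of these probes cannot be told apart from labelling or hybridization that differed between arrays. Before normalization the median knockdown difference over all miRNAs was 1.78 on the log2 scale in SCC9 and 0.74 in CAL27. Quantile normalization brought these medians to 0.02 and 0.01, and the changes below are relative to that.

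**Figure D1:**
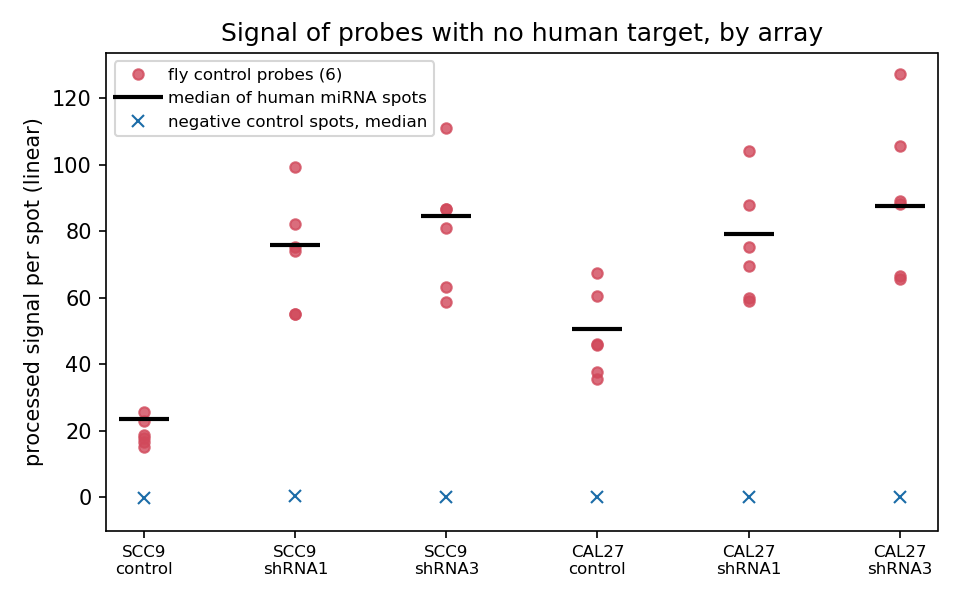
Processed signal per spot (linear intensity, 1 array per position) of 6 fly control probes (points), the median human miRNA spot (bars) and the median negative control (crosses). The fly probes and the median human spot are lowest on the control array of each line, while the negative controls stay near 0.

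Both arms of miR-483, a miRNA encoded on chromosome 11 (2134134 to 2134209) within the span of the growth factor gene IGF2, were far higher in the hairpin cells. In SCC9 miR-483-5p rose 457-fold (log2 8.84, SE 0.05, adjusted p = 7.42e-05) and miR-483-3p rose 511-fold (9.00, SE 0.04, adjusted p = 7.28e-05). In CAL27 miR-483-5p rose 68.6-fold (6.10, SE 0.05) and miR-483-3p 23.8-fold (4.57, SE 0.04), both at adjusted p = 0.000371. Each arm was higher on all 4 hairpin arrays. Both arms had the same normalized value on the 2 SCC9 hairpin arrays, since quantile normalization goes by rank, and the 3p arm on the 2 CAL27 ones as well. So the SE of the 3p arm within the lines comes from limma's prior alone, and that of the 5p arm from the prior and the CAL27 pair. The signal of miR-483-5p went from 81.9 on the SCC9 control to 41537 with shRNA1 and 40309 with shRNA3, where it ranked 3 among all miRNAs and made up 8.05% and 7.19% of the signal. In CAL27 it went from 84.5 to 7506 and 8669. The 3p arm went from 8.14 to 6324 and 6404 in SCC9 and from 15.2 to 525 and 586 in CAL27, and on both control arrays it lay below the median of all entries (0.961 and 0.847 times), so its folds are set by the floor of those arrays. The direction was the same under each of the 6 scalings tried, with SCC9 values of 7.77 to 9.63 for the 5p arm and 8.41 to 10.03 for the 3p arm.

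**Figure D2:**
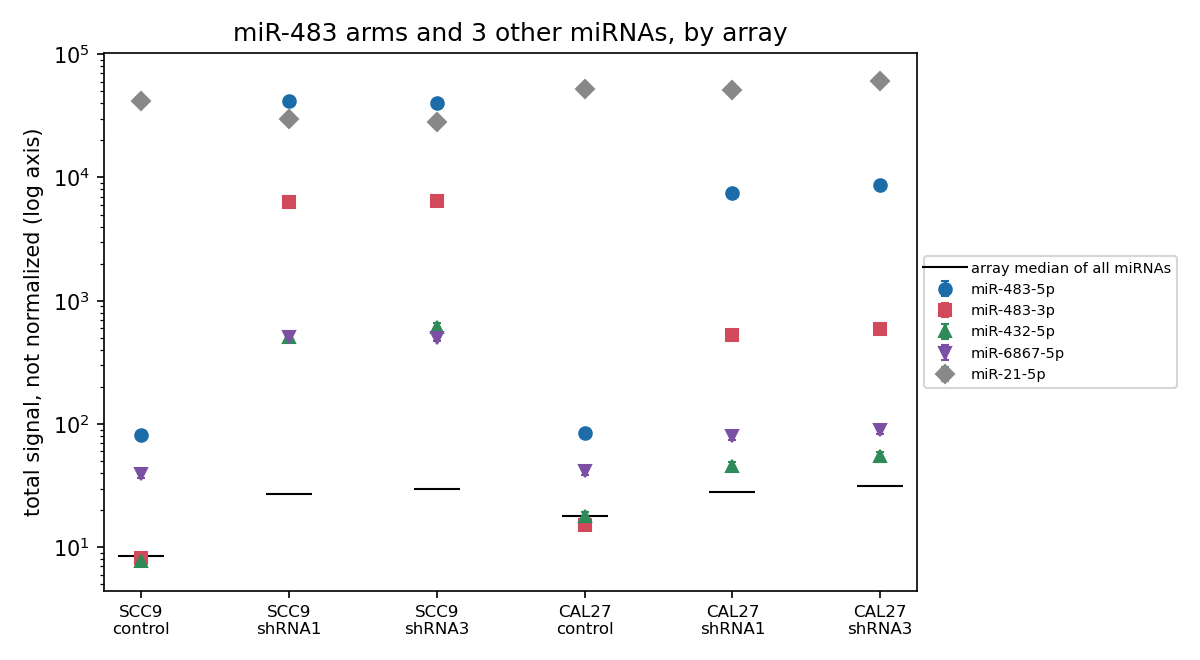
Total signal before normalization (log axis, intensity units) of miR-483-5p, miR-483-3p, miR-432-5p, miR-6867-5p and miR-21-5p on each of 6 arrays, with the signal error of the scanner software as bars and the array median as a line. Both miR-483 arms lie near or below 84.5 on the controls and between 525 and 41537 on the hairpin arrays.

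In the contrast over both lines, with cell line as a term, limma called 0 of 2549 miRNAs higher and 0 lower, and 587 had an unadjusted p under 0.05. MiR-483-5p was 177-fold higher (7.47, SE 0.65) and miR-483-3p 110-fold higher (6.78, SE 1.04), each at adjusted p = 0.0755. Adjusted over the list alone, both arms passed (0.000319 and 0.00188), but the study chose this pair on these samples, so that count is not independent evidence. Here the spread includes the difference in response between the lines. Without 1 of the 4 hairpin arrays 0 or 1 miRNAs were called, the 1 without SCC9 shRNA3. Each line has a single control, so without it the contrast rests on the other line: without the SCC9 control it gave the 2 CAL27 calls, both miR-483 arms, and without the CAL27 control 100, as in SCC9 under that setting.

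Of the other miRNAs that went the same way on all 4 hairpin arrays, none passed over both lines. The higher ones included miR-205-3p, the minor arm of a squamous epithelial miRNA (3.81-fold, adjusted p = 0.126), miR-432-5p (8.08-fold, 0.178), miR-6867-5p (4.33-fold, 0.168) and miR-572 (2.75-fold, 0.0921). MiR-372-3p, an embryonic stem cell miRNA, miR-2114-5p, miR-4299, miR-6729-5p, miR-548q and miR-4470 were 1.94-fold to 2.22-fold higher. Without normalization none of this last group exceeded the largest fly probe shift on the SCC9 hairpin arrays (2.21 and 2.29 log2 units). On both CAL27 hairpin arrays only miR-2114-5p and miR-4299 of this group exceeded it (0.75 with shRNA1 and 0.96 with shRNA3). The lower ones included miR-4485-3p, an entry that matches mitochondrial ribosomal RNA (2.63-fold, 0.0809), and miR-203a-3p, which restrains the stemness factor p63 in stratified epithelium (1.98-fold, 0.203). MiR-6779-5p, miR-504-3p, miR-4534, miR-1587, miR-6785-5p, miR-6774-5p, miR-642a-3p and miR-4522 were 1.49-fold to 2.17-fold lower, with adjusted p = 0.0755. All of these but miR-6785-5p and miR-642a-3p were dim. Of the dim ones, miR-504-3p, miR-6774-5p and miR-4522 were higher with no normalization or with scaling on bright miRNAs, and miR-4534 with the latter.

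In SCC9, 58 miRNAs were called higher and 50 lower after quantile normalization, and 30 of these 108 were bright (18 higher, 12 lower). Of the 58, 53 stayed above 0 under all 6 scalings, but only 8 of the 50 stayed below 0. So the direction of most lower calls depends on the scaling. Tested among bright miRNAs alone, 8 passed as higher and 0 as lower, and 36 and 0 with scaling on bright miRNAs too, so no bright fall kept its call in these 2 settings. In the first only the test differs and the changes are the same, with miR-132-3p still at -1.45 (adjusted p = 0.0531). The control side of this test is 1 array, so its own variation is not in the spread. Before normalization 14 of the 18 bright rises did not exceed the largest fly probe shift on both hairpin arrays, and only the miR-483 arms, miR-432-5p and miR-6867-5p did. Beside miR-483, the largest rises were of miR-432-5p, from the imprinted DLK1-DIO3 region of chromosome 14 (35.7-fold, log2 5.16, SE 0.10, adjusted p = 0.00351; at 0.918 times the median on the SCC9 control, so the floor sets this fold), miR-6867-5p (11.8-fold, 3.56, SE 0.13, adjusted p = 0.0131) and miR-572 (4.36-fold, 2.13, SE 0.05, adjusted p = 0.00631). Before normalization the rise of miR-572 was below the median shift of the fly probes on both arrays (1.88 against 1.91 on shRNA1, and below 2.09 on shRNA3). MiR-132-3p, which the transcription factor CREB induces, fell by 1.45 on the log2 scale (SE 0.09, adjusted p = 0.0287), also under each of 6 scalings (-2.12 to -0.50). Its signal was 48.7 and 50.5 on the SCC9 hairpin arrays, where the medians were 27.1 and 30.0. So the size of this fall depends on the floor there. MiR-6779-5p (-1.45, adjusted p = 0.0131) and miR-504-3p (-1.25, adjusted p = 0.0179), both dim, were called lower too. They lay below the median signal on both SCC9 hairpin arrays, so the floor sets these changes. MiR-6779-5p was at 0.16 with scaling on bright miRNAs, and miR-504-3p was at 0.89 with no normalization and at 1.31 with that scaling. MiR-4485-3p (-1.35, adjusted p = 0.154) and the tumour suppressor miR-7-5p (-1.29, adjusted p = 0.0787) were lower on both hairpin arrays and did not pass.

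The SCC9 calls depended on scaling and on single arrays. The split of higher to lower calls was 2200 to 127 with no normalization, 1683 to 460 with the 75th percentile over all miRNAs, 2271 to 36 with scaling on bright miRNAs and 196 to 361 with cyclic loess. The first 3 of these scalings move the median SCC9 difference over all miRNAs up (to 1.78, 0.59 and 2.21), so their splits depend on where 0 lies. Not every miRNA moves up with them: miR-483-5p went from 8.84 to 7.77 with the 75th percentile. The spread in the test is pooled over both pairs of hairpin arrays, and the differences between the hairpins had an SD of 0.16 log2 units over bright miRNAs in CAL27 against 0.76 in SCC9. Without CAL27 shRNA1 or without CAL27 shRNA3 there were 2 calls, without SCC9 shRNA1 357, and with the SCC9 arrays alone 2. In each setting with 2 calls these were the miR-483 arms. The SCC9 control was in row 1 of the slide and both SCC9 hairpin arrays in row 2. So the SCC9 contrast cannot be told apart from slide row, while all CAL27 arrays were in row 1.

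In CAL27 only the miR-483 arms passed among 2549 (2 higher, 0 lower, 315 with an unadjusted p under 0.05). Without either CAL27 hairpin array their calls were lost as well, with changes of 6.02 and 6.03 for miR-483-5p and of 4.61 and 4.62 for miR-483-3p. The pair of hairpin arrays left was then the SCC9 one, where each arm had tied normalized values. So the spread in that test was limma's prior, estimated over all miRNAs from the SCC9 pair. MiR-205-3p (2.32-fold higher, adjusted p = 0.573), miR-7106-5p (2.05-fold, 0.115) and miR-4299 (2.01-fold, 0.401) were higher with both hairpins and did not pass. MiR-4446-3p, miR-4459, miR-4697-5p, miR-4485-3p and miR-1973, the last a fragment of mitochondrial RNA, were 2.20-fold to 2.70-fold lower with both hairpins and did not pass either (adjusted p from 0.379 to 0.506).

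**Figure D3:**
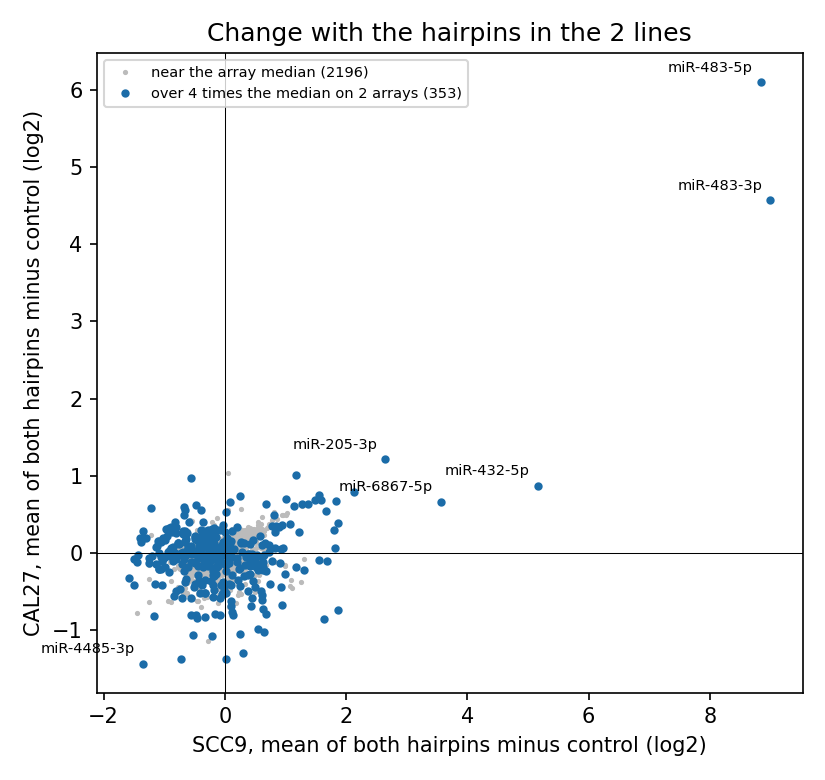
Mean hairpin minus control difference (log2) in SCC9 (horizontal) and CAL27 (vertical), 1 point per miRNA, with bright miRNAs in blue and dim ones in grey. The miR-483 arms stand far from all other points, at 8.84 and 9.00 in SCC9 and 6.10 and 4.57 in CAL27.

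The response differed between the lines for 3 miRNAs, all with a smaller rise in CAL27, and for 310 at an unadjusted p under 0.05. The difference (CAL27 minus SCC9) was -4.43 for miR-483-3p (SE 0.06, adjusted p = 0.00271), -4.29 for miR-432-5p (SE 0.14, adjusted p = 0.0217) and -2.74 for miR-483-5p (SE 0.07, adjusted p = 0.0135). Both CAL27 hairpin arrays lay below both SCC9 hairpin arrays for each. The values of miR-483-3p and miR-432-5p depend on the floors of the controls, where both were near or below the median (0.961 and 0.847 times for miR-483-3p, 0.918 times in SCC9 for miR-432-5p) and which differ between the lines (8.47 against 18.0). The largest differences the other way were of miR-10b-5p (1.80, SE 1.18), of miR-146a-5p, which NF-kB induces (1.62, SE 1.81), and of miR-200a-3p (1.59, SE 1.67) and miR-429 (1.55, SE 1.53), which hold epithelial identity by targeting ZEB1, and none passed (adjusted p from 0.592 to 0.721). These rest largely on the SCC9 shRNA3 array. Against the SCC9 control the 4 miRNAs were at -0.34, 0.03, -0.13 and -0.20 with shRNA1. With shRNA3 they were at -2.09, -2.71, -2.65 and -2.51, in the same order. Without either CAL27 hairpin array 0 miRNAs passed, without SCC9 shRNA3 1 and without SCC9 shRNA1 159. Row 2 of the slide held only the SCC9 hairpin arrays, so a different response of the lines cannot be told apart from slide row.

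Among the miRNA groups, let-7, a tumour-suppressive family, was lower in SCC9: 9 of 9 members had a negative change (median -0.53), and 1 of them, let-7a-5p, fell (-0.82, adjusted p = 0.0246), both over all miRNAs and adjusted over the list alone. The family passed camera (adjusted p = 0.0371), but not with an estimated correlation (adjusted p = 0.851 with an estimated correlation), nor with cyclic loess (0.966), where let-7a-5p was at 0.25, nor without CAL27 shRNA1 (0.0576) or without CAL27 shRNA3 (0.0504). The cisplatin response literature list was likewise lower in SCC9, with 14 of 17 members negative (median -0.30, camera adjusted p = 0.0413, but adjusted p = 0.851 with an estimated correlation, 0.928 with cyclic loess, and 0.0576 and 0.0504 without those same CAL27 arrays). Its called member, again 1 adjusted over the list alone, was miR-21-5p, an oncogenic miRNA (-0.65, adjusted p = 0.0287, but 0.57 with cyclic loess). MiR-21-5p ranked 3 on the SCC9 control and 4 on both SCC9 hairpin arrays, where miR-483-5p ranked 3. So its normalized fall is that step of rank. Its values were tied between the hairpins of each line, so its SE comes from limma's prior alone. Without normalization it fell by 0.50 and 0.57 on the log2 scale with shRNA1 and shRNA3. With bright miRNAs alone neither list passed camera (0.373 and 0.410), while with bright miRNAs alone that were also scaled on bright miRNAs both did (both 0.00278).

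GC-rich entries known for high background were lower in CAL27 hairpin cells, with 18 of 19 negative (median -0.41), though no single member passed, over all miRNAs or adjusted over the list alone. The list passed camera (adjusted p = 0.000297; adjusted p = 0.963 with an estimated correlation), and its median was below 0 under all 6 scalings. Its largest changes were of miR-5787 (-0.83), miR-4281 (-0.80), miR-6090 (-0.80) and miR-4516 (-0.69). In SCC9 the same list had a median of -0.02 (camera adjusted p = 0.724), which ran from -1.31 with the 75th percentile to 0.31 with scaling on bright miRNAs and was below 0 under 5 of 6 scalings. Over both lines no list passed camera, the lowest being these entries and the cisplatin list, both at adjusted p = 0.0957.

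The other groups did not pass camera in SCC9. Regulators of mitochondrial fission had a median of -0.24 but a mean of 0.46, set by miR-483-5p, 1 of 12 members called (adjusted over the list alone, 1 higher and 3 lower; camera adjusted p = 0.241). The list was built around the study's own claim for miR-483-5p, so its direction is not independent evidence, and its median was above 0 with no normalization (0.68) and with scaling on bright miRNAs. The 5 NF-kB and inflammation miRNAs were all negative (median -1.34, camera adjusted p = 0.0503), with miR-21-5p the 1 called and miR-9-5p (-1.58), miR-155-5p (-1.50) and miR-146a-5p (-1.34) not. The call of miR-21-5p has the limit of rank given above. The hairpins did not agree here: miR-155-5p was at -0.41 with shRNA1 and -2.60 with shRNA3, and miR-146a-5p at 0.03 and -2.71. The miR-183 cluster was at a median of -1.08 (0 of 3 called, 2 adjusted over the list alone), the miR-320 family at -0.45 (0 of 6, 4) and miR-17-92 with its paralogs at -0.20 (1 of 12, miR-17-5p, and 2), each at camera adjusted p = 0.0503. In the squamous epithelium list 1 of 11 was called (1 higher and 1 lower adjusted over the list alone), miR-205-5p (-0.68, adjusted p = 0.0287, but 0.05 with cyclic loess), beside miR-203a-3p (-1.17), miR-224-5p (-0.97) and miR-944 (-0.65), which did not pass (camera adjusted p = 0.374). MiR-205-5p went from rank 5 on the SCC9 control to rank 8 on both SCC9 hairpin arrays. Its values were tied between the hairpins of each line, so its SE too comes from limma's prior alone. In the p53 and DNA damage list 0 of 15 passed (1 higher adjusted over the list alone), with miR-34b-5p at -1.42, miR-194-5p at -1.26 and miR-34c-5p at -1.25 (median -0.71, camera adjusted p = 0.152).

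Oral carcinoma oncomiRs had a median of -0.43 (camera adjusted p = 0.241). Of 13, 1 was called, again miR-21-5p with that limit of rank (adjusted over the list alone, 2 higher and 1 lower). Its opposite arm miR-21-3p was at 1.80 (adjusted p = 0.0550). Oral carcinoma suppressors were at 0.00 (0 of 18 called, 0.724). The miR-200 family was at -0.67 (0 of 8, 0.724), the miR-23-27-24 clusters at -0.35 (0 of 5, 0.152), miR-221 with miR-222 at -0.36 (0 of 4, 0.357), miR-15-16-195 at -0.19 (0 of 7, 0.307), miR-29 at -0.08 (0 of 5, but 1 higher adjusted over the list alone, 0.803) and the miR-99, miR-100 and miR-125 group at 0.03 (0 of 7, 0.724). Of the 7 interferon and stress miRNAs 1 rose, miR-663a (0.52, adjusted p = 0.0388; camera adjusted p = 0.724). Entries that are fragments of other RNAs were at 0.01 (0 of 10, 0.855). The hypoxia miRNA miR-210-3p was at 0.02 in SCC9 and 0.54 in CAL27 and did not pass in either. With scaling on bright miRNAs the medians of the miR-200, miR-29, miR-320 and miR-221 groups in SCC9 were above 0.

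Markers of other cell types did not pass camera in SCC9. Medians were -0.09 for blood (0 of 7 called, camera adjusted p = 0.724), 0.02 for fibroblasts and mesenchyme (0 of 10, 0.859), -0.01 for muscle (0 of 6, 0.769) and -0.14 for liver and neuron miRNAs (0 of 6, 0.769). Adjusted over the list alone, 1 muscle miRNA was higher and 1 lower, and 2 of the liver and neuron list were higher and 1 lower. For change in either direction these 2 lists (fry adjusted p = 0.0199 and 0.00400) and the mesenchymal one (0.00471) passed, and blood did not (0.0687). With no normalization the first 3 of these medians were 1.42, 1.86 and 1.74, near the shift of all miRNAs, and the last was above 0 as well. The endothelial miR-126-3p was at 0.92 and did not pass. Of 13 embryonic and C19MC miRNAs 1 rose, miR-372-3p (1.49, adjusted p = 0.0426; camera adjusted p = 0.319), which before normalization was 1.93 and 1.97 higher, within the fly probe shifts of those arrays (1.72 to 2.21 and 1.83 to 2.29). In CAL27 no member of any list was called except the miR-483 arms, and no list passed camera except the GC-rich entries.

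The directional test of fry, which asks whether a list moves on balance and does not compare it with other miRNAs, gave other calls in the knockdown. Over both lines miR-221 and miR-222 passed it (lower, adjusted p = 0.0306). In SCC9 miR-17-92 with its paralogs (lower, 0.0335) and the fission regulators (higher, 0.00596, against their negative median and camera direction) passed, and in CAL27 the fission regulators (higher, 0.00239). With miR-483-5p taken out of that list, a fit added after the results were seen, it did not pass in SCC9 (lower, 0.0862) or CAL27 (higher, 0.520). Neither let-7 nor the cisplatin list passed fry in SCC9 (both 0.0862), nor the GC-rich entries in CAL27 (0.921). For change in either direction fry called 5 of 25 lists over both lines, 15 in SCC9, 2 in CAL27 and 15 between the lines.

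Between the lines, 84 miRNAs were higher and 74 lower in CAL27 than in SCC9 (547 with an unadjusted p under 0.05), 44 and 37 of them bright. Higher in CAL27 were the p53-induced epithelial miRNAs miR-192-5p (6.02-fold, SE 0.33 log2 units, adjusted p = 0.0260), miR-215-5p (5.60-fold) and miR-194-5p (4.55-fold). So were both arms of miR-30a, miR-30a-3p (6.57-fold, SE 0.44, adjusted p = 0.0428) and miR-30a-5p (5.06-fold), and miR-93-5p of the miR-106b-25 cluster (5.92-fold, SE 0.19, adjusted p = 0.00777). MiR-200c-5p, miR-221-5p, miR-7-1-3p, miR-30e-3p, miR-29c-3p and miR-101-3p, the last a repressor of EZH2, were 3.19-fold to 3.85-fold higher. Much lower in CAL27 were miR-8089 (91.5-fold, log2 -6.52, SE 0.39, adjusted p = 0.00672) and miR-3934-5p (49.4-fold, -5.63, SE 0.38, adjusted p = 0.00773), encoded on chromosomes 5 (181043403 to 181043484) and 6 (33698128 to 33698234). MiR-6726-5p, miR-584-5p, miR-150-3p, miR-365b-5p, miR-4487, miR-7845-5p, miR-630, miR-1268a, miR-658 and miR-198 were 4.04-fold to 7.98-fold lower. These 24 were picked as having no overlap between the arrays of the lines. On the CAL27 arrays miR-8089 was at 1.30 to 1.66 times the median and miR-3934-5p at 1.61 to 2.23 times, so their folds depend on the nonspecific signal there. In all, 10 of the 12 lower miRNAs were at most 4 times the median on all 3 CAL27 arrays, and 1 of the 12 higher ones, miR-200c-5p, on all 3 SCC9 arrays.

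**Figure D4:**
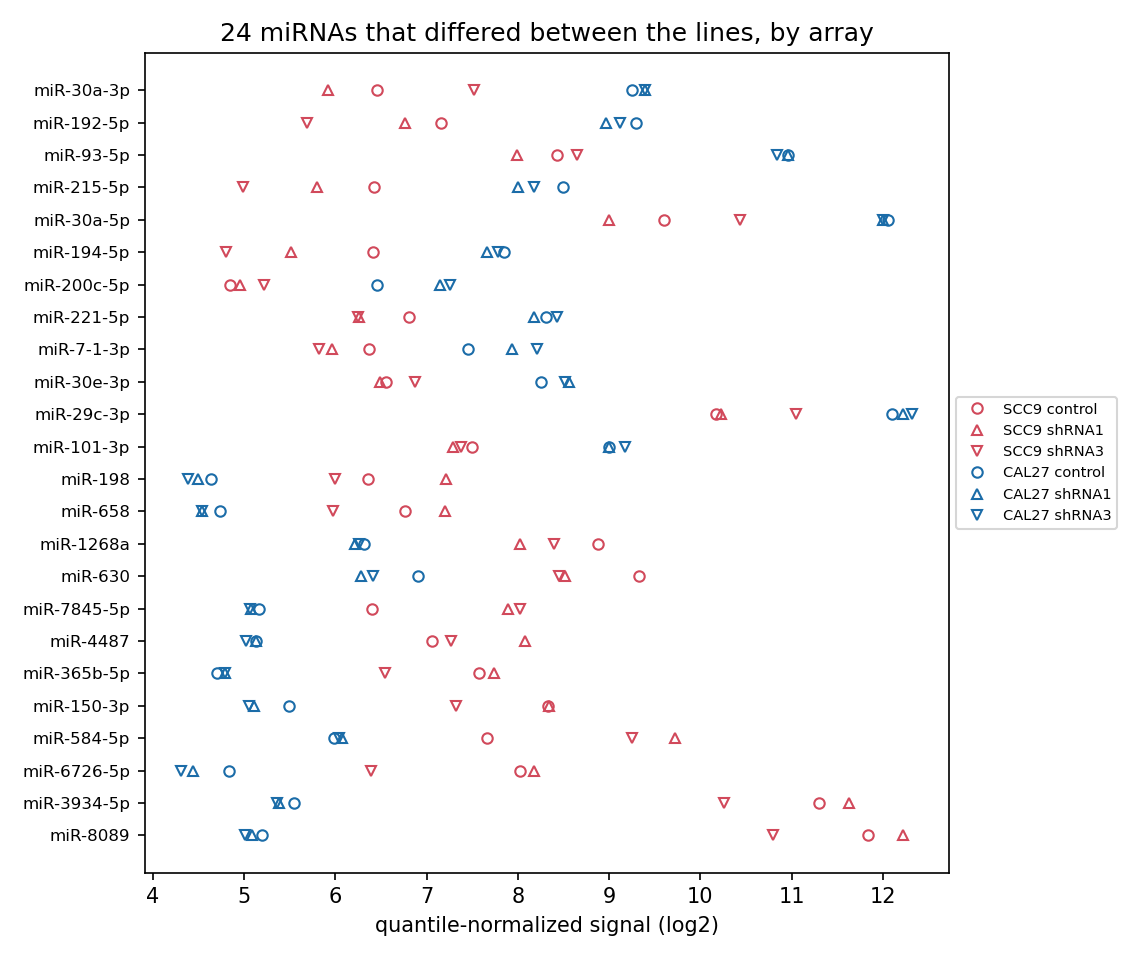
Quantile normalized signal (log2) of 24 miRNAs that differed between the lines, on 3 SCC9 (red) and 3 CAL27 (blue) arrays, with circles for controls and triangles for hairpins. The SCC9 and CAL27 symbols do not overlap for any of the 24, and miR-8089 and miR-3934-5p are the farthest apart.

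As groups, miR-29, which represses collagens, was higher in CAL27 (5 of 5 positive, median 1.19, 3 called, 4 adjusted over the list alone; camera adjusted p = 0.000511, but adjusted p = 0.388 with an estimated correlation). Its called members were miR-29c-3p (1.73), miR-29b-1-5p (1.39) and miR-29a-3p (1.19). MiR-221 and miR-222, which repress the cell cycle inhibitor p27, were higher too (4 of 4 positive, median 0.63, 3 called, 3 adjusted over the list alone; camera adjusted p = 0.00129, but adjusted p = 0.388 with an estimated correlation). MiR-17-92 and its paralogs passed camera at adjusted p = 0.0316 (adjusted p = 0.719 with an estimated correlation), with 8 of 12 positive and 3 called, miR-93-5p, miR-25-3p (0.69) and miR-19a-3p (0.32), 3 also adjusted over the list alone. GC-rich high-background entries were lower (16 of 19 negative, median -0.81, 7 called, 13 adjusted over the list alone; camera adjusted p = 2.37e-08, but adjusted p = 0.719 with an estimated correlation), with miR-1268a (-2.17), miR-5787 (-1.85) and miR-6087 (-1.83) the farthest. The medians of these 4 lists kept their sign under all 6 scalings, but with bright miRNAs alone only the GC-rich entries passed (camera adjusted p = 0.141 for miR-29, 0.404 for miR-221 and miR-222, 0.470 for miR-17-92). With bright miRNAs alone that were also scaled on bright miRNAs, miR-29 (adjusted p = 0.0265) and miR-17-92 (0.0111) passed, and miR-221 and miR-222 (0.137) did not.

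Other lists did not pass camera between the lines, though some members did. By fry, miR-29 and miR-221 with miR-222 (both adjusted p = 0.000481) and the GC-rich entries (0.0229) passed, as did the oral carcinoma suppressors (higher, 0.0178), and miR-17-92 did not (0.109). Oral carcinoma oncomiRs held 3 called members of 13, miR-31-5p (1.09), miR-31-3p (0.82) and miR-222-3p (0.72), all higher in CAL27, and the squamous list both miR-31 arms of 11. The fission regulators held miR-30a-5p (2.34) and miR-30c-5p (1.24) of 12, the p53 list miR-192-5p, miR-215-5p and miR-194-5p of 15, the miR-15-16-195 family miR-15a-5p (1.07) of 7, and the miR-200 family miR-200c-5p of 8. Let-7f-5p was called in let-7 (0.55), but was at -0.0050 with cyclic loess. The cisplatin list held miR-93-5p, miR-31-5p and miR-222-3p of 17, and the oral carcinoma suppressors miR-29a-3p and miR-29c-3p of 18. Adjusted over the list alone, the counts were 3 for the fission regulators, 3 higher and 2 lower for the oncomiRs and for the suppressors, and unchanged for the p53, squamous, cisplatin, miR-15, miR-200 and let-7 lists. No member of a list of other cell types was called between the lines, though for change in either direction fry called the mesenchymal list (adjusted p = 0.00710). Without either CAL27 hairpin array the cell line calls fell to 7 and 9, and without SCC9 shRNA1 and SCC9 shRNA3 they were 104 and 247. MiR-17-92 lost its call without any 1 of the 4 hairpin arrays (adjusted p from 0.0679 to 0.130). With the row of the slide as a block 0 were called, but row 2 held only the SCC9 hairpin arrays, so that fit compares the lines without them.

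The hairpins differed for 0 miRNAs in limma's test, with 10 at an unadjusted p under 0.05. The largest differences with the same sign in both lines were of miR-126-3p (1.54, SE 0.78), miR-125b-5p (0.68, SE 0.38) and miR-99a-5p (0.64, SE 0.32), higher with shRNA3, and of miR-155-5p (-1.13, SE 0.72), miR-6726-5p (-0.96, SE 0.45) and miR-8089 (-0.75, SE 0.37), lower with it, each at an adjusted p of 1. These differences came almost wholly from SCC9. Against the control, shRNA1 and shRNA3 gave -0.54 and 2.38 for miR-126-3p in SCC9, but -0.04 and 0.13 in CAL27. For miR-155-5p they gave -0.41 and -2.60 in SCC9, but -0.04 and -0.12 in CAL27. MiR-483-5p differed by -0.03 (SE 0.85). On single arrays against the control of their line, 36 miRNAs were at least 2-fold higher and 9 lower with SCC9 shRNA1, 62 and 76 with SCC9 shRNA3, 5 and 7 with CAL27 shRNA1 and 5 and 11 with CAL27 shRNA3.

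Both arms of miR-483 moved together. Across 810 precursors with both arms measured, the knockdown changes of the 5p and 3p arms had a Pearson r of 0.53 and a Spearman rho of 0.07. Without miR-483 the r over the other 809 was 0.04, so the pooled value rests on that precursor. These are correlations across miRNAs, which are not independent replicates. The sign was the same for both arms in 52.8% of precursors. Over the 23 other precursors with both arms bright it was the same in 65.2%, with an r of -0.03 and a rho of 0.02, and their r and rho were -0.16 and 0.07 in SCC9 and 0.63 and 0.31 in CAL27.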

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

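The tests of technical explanations below were chosen after the results were seen, except the count of other splits of the arrays, which was planned.

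The knockdown response differed between the lines for 3 miRNAs by limma's test of that difference. The CAL27 minus SCC9 value was -4.43 for miR-483-3p, -4.29 for miR-432-5p and -2.74 for miR-483-5p, each a smaller rise in CAL27. The values of miR-483-3p and miR-432-5p depend on the floors of the control arrays. Slide row cannot be told apart from this difference, since row 2 held only the SCC9 hairpin arrays. Without either CAL27 hairpin array none of the 3 passed. Over all alternatives the values kept their sign, at -4.96 to -3.75 for miR-483-3p, -5.22 to -3.94 for miR-432-5p and -3.21 to -1.71 for miR-483-5p. A signal also appeared in probes outside the main measurement. The median fold of 6 fly control probes over the control of the line was 3.76 on SCC9 shRNA1, 4.25 on SCC9 shRNA3, 1.55 on CAL27 shRNA1 and 1.88 on CAL27 shRNA3. Dim human entries (2105 below 4 times the median on every array) moved alike, with median folds of 3.50, 3.87, 1.59 and 1.80, while the 195 miRNAs bright on all 6 arrays had folds of 0.694, 0.869, 1.01 and 1.21.

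Both miR-483 arms were higher on all 4 hairpin arrays. Lower nonspecific signal on the controls was argued against, since the unnormalized rise exceeded the largest fly probe shift of the same array by at least 4.30 log2 units over both arms and 4 arrays. RNA of other cells was argued against too: 0 of 44 miRNAs typical of blood, mesenchyme, endothelium, muscle, liver, neurons or embryonic and placental cells rose over 2-fold beyond that shift on all 4 arrays. The abundant liver miRNA miR-122-5p stayed between 22.5 and 27.8. Silencing of the long noncoding RNA may account for the rise, as a hypothesis; an effect of transduction or of carrying a hairpin remains open, because the labels do not say what the control cells carried.

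Of the 108 miRNAs called in SCC9, 78 were dim. Nonspecific signal that differs between the control and hairpin arrays may account for these, and 67 of the 78 (85.9%) changed the same way in CAL27, where the fly probes shifted the same way by less, against 66.7% of dim entries that were not called. Their median change was 0.59 (higher) and -0.60 (lower) in SCC9 and 0.30 and -0.23 in CAL27. That cannot be told apart from a shared response to the knockdown, since both hairpin arrays of each line had the higher nonspecific signal. Before normalization 75 of the 78 lay between the median shift of the miRNAs bright on all 6 arrays and the largest fly probe shift, and 3 lay outside that range on both SCC9 hairpin arrays, 1 of them not detected on the SCC9 control. Nearly all dim entries that were not called lay within it too (2102 of 2118), so that count does not set the calls apart. Of the 30 bright calls 4 lay above, 9 below and 17 within. Those within include 14 of the 18 bright rises, miR-572 and miR-372-3p among them, so nonspecific signal stays open for these as well.

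MiR-432-5p and miR-6867-5p were higher where miR-483 was. A fixed share of miR-483-5p bound by their probes was argued against, because the lowest such share on SCC9 hairpin arrays was 2.95 times the highest on CAL27 hairpin arrays for miR-432-5p and 1.70 times for miR-6867-5p. A fixed share of miR-483-3p was argued against only weakly for miR-432-5p (1.29 times). The range covers the nonspecific shift and not the signal error, and the share was 7.66% and 9.11% on the SCC9 hairpin arrays. For miR-6867-5p it was not argued against (0.710 times), as the ranges overlap and this cannot be told apart from a change of the miRNA itself. A rise of the whole miR-432 cluster was argued against, as 0 of 6 other arms rose beyond the fly probes on both SCC9 hairpin arrays. A change in these miRNAs with the knockdown, and binding to their probes that is not in proportion, may each account for the rest and were not tested.

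For the 158 miRNAs called between the lines, 1 of the 10 splits of 6 arrays into 3 and 3 gave as many, the real one, and the highest of the others gave 3. So few splits cannot give a share under 0.05.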

How the results depend on the processing

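Bright miRNAs alone, scaling on bright miRNAs, both together, single lines and the slide row were chosen after the data were seen. The cause of each change below was not tested, unless stated. Leaving aside the knockdown results of miR-483, of 73 results for single named miRNAs 66 never reversed; of the 33 called, none was called under every alternative. MiR-483-5p and miR-483-3p in SCC9 passed under all 22 alternatives. The hairpin count stayed at 0 in all 22. Among these alternatives, a floor 2 times lower, detection on at least 1 array and no filter gave the counts of the main fit in every contrast.

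With the 75th percentile over all miRNAs, the knockdown called 1716, SCC9 2143, CAL27 18 and the line difference 1583, and over detected miRNAs 1721, 2138, 18 and 1558. With no normalization these were 2046, 2327, 1973 and 2029, and with scaling on bright miRNAs 1958, 2307, 1960 and 2254, with 57 between the lines. These settings leave or add the nonspecific shift: the median knockdown change over all miRNAs was 0.40, 1.25 and 1.42 with the percentile, no normalization and bright scaling. Between the lines it was 0.17, 0.43 and -0.11, and the split of calls was 138 higher to 35 lower with no normalization and 20 to 37 with bright scaling.

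Cyclic loess called 557 in SCC9 and 6 for the line difference. Mean processed signal gave 5 in CAL27, and normexp 4 in CAL27 and 7 for the line difference. A trended robust prior gave 2 in the knockdown, 301 in SCC9 and 4 in CAL27. The deposited table gave 181 in SCC9 and 5 for the line difference. Bright miRNAs alone gave 1 in the knockdown, 8 in SCC9 (8 higher, 0 lower) and 92 between the lines (fewer tested), with bright scaling too 1 and 36 (36 higher, 0 lower). SCC9 arrays alone gave 2. The slide row as a block gave 2 in the knockdown, which are the CAL27 calls since row 2 held only the SCC9 hairpin arrays, and 0 between the lines. The shRNA3 arrays with controls gave 0 between the lines.

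MiR-483-5p and miR-483-3p passed in the knockdown over both lines at 6.91 and 6.54 with either percentile, 7.77 and 7.40 with no normalization, and 7.93 and 7.55 with bright scaling. The slide row as a block gave 6.10 and 4.57, the values of CAL27 alone. MiR-483-5p alone passed at 7.47 with the robust prior and with bright miRNAs alone, and at 7.93 with bright scaling and bright miRNAs alone.

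Lists called with either percentile were 19 in the knockdown, 20 in SCC9 and 19 in CAL27. With no normalization they were 19, 20 and 20, and 12 between the lines; with bright scaling 20, 21, 19 and 12. Cyclic loess gave 0 in SCC9 and normexp 6. Bright miRNAs alone gave 0 in SCC9 and 1 between the lines, and with bright scaling 3 in the knockdown and 7 in SCC9. The shRNA1 arrays with controls gave 3 in the knockdown. With an estimated correlation, 0 lists passed in SCC9, CAL27 or between the lines.

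On single arrays the 2-fold count over all miRNAs was 376 for SCC9 shRNA1, 291 for SCC9 shRNA3, 30 for CAL27 shRNA1 and 38 for CAL27 shRNA3 with the 75th percentile (378, 291, 30 and 38 over detected miRNAs). With no normalization it was 1950, 2113 and, for CAL27 shRNA3, 64, and with bright scaling 2134 and 2236 in SCC9. Cyclic loess gave 74 for SCC9 shRNA1, and normexp 7 for CAL27 shRNA1. In that order of arrays, a 1.5-fold limit gave 185, 284, 57 and 76, and a 3-fold limit 17, 39, 2 and 4. The r between arms was 0.29 with either percentile, 0.28 with no normalization or bright scaling, 0.58 with normexp, 0.89 with bright miRNAs alone (-0.03 without miR-483), 0.85 with bright scaling too and 0.41 with SCC9 arrays alone.

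Values that reversed were miR-504-3p (0.53 in the knockdown and 0.89 in SCC9), miR-6774-5p (0.21) and miR-4522 (0.34) with no normalization. With bright scaling they were miR-504-3p (0.69 and 1.31), miR-6774-5p (0.36), miR-4522 (0.50), miR-4534 (0.0098) and miR-6779-5p in SCC9 (0.16). The hairpin value of miR-155-5p was 0.011 without SCC9 shRNA3 (range -2.26 to 0.011 over arrays left out).

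Leaving out each array gave 0 to 100 calls in the knockdown, but 0 to 1 over the hairpin arrays, since without a control that contrast is the one of the other line. It gave 2 to 357 in SCC9, 0 to 2 in CAL27, 0 to 159 for the line difference and 7 to 247 between the lines. Lists ran from 0 to 6 in the knockdown (0 to 1 over the hairpin arrays), 0 to 9, 1 to 1 and, between the lines, 3 to 11. MiR-483-5p ran from 6.09 to 8.81 in the knockdown (7.33 to 7.63 over the hairpin arrays) and 6.02 to 6.23 in CAL27, miR-483-3p from 4.38 to 8.83 (6.60 to 7.09) and 4.38 to 4.69, and the arm correlation from 0.42 to 0.57. A line left with 1 hairpin array is assumed to vary like the other line. Detection on at least 1 array and no filter removed no miRNA and test nothing. The floor 2 times lower left every count of called miRNAs as it was. The slide as a block was not run, with 1 slide. The arrays of a line are matched by the cell line term, and no block on replicate numbers could be fitted, because every group holds 1 sample. Signal over background limits the dim entries.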

Other observations

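The values below were looked up after the main results were seen, and no explanation was tested for them.

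Both lines carried miRNAs of squamous epithelium at high signal, here before normalization. MiR-205-5p, which marks stratified epithelium, was at 19189 units on the SCC9 control and 15982 on the CAL27 control, and the oncogenic miR-21-5p at 41924 and 52546. MiR-200c-3p, which holds epithelial identity, was at 3456 and 5108, and miR-31-5p, abundant in oral carcinoma, at 1747 and 4318. MiR-375, a miRNA lost in many head and neck carcinomas, was at 10.7 and 24.0, near the array medians of 8.47 and 18.0. Of 31 markers of other cell types, 24 were over 4 times the median on no array, and 2, miR-9-3p and miR-486-5p, on all 6. The blood miRNA miR-223-3p was at 19.9 and 33.5 and the mesenchymal miR-143-3p at 6.57 and 15.1.

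Some abundant miRNAs separated the SCC9 hairpins from each other. The signal of miR-155-5p, an inflammatory miRNA, was 628 on the SCC9 control, 406 with shRNA1 and 124 with shRNA3, against 1339, 1228 and 1486 in CAL27. MiR-34a-5p, induced by p53, was at 389, 327 and 131 in SCC9 and at 298, 312 and 402 in CAL27. There is 1 array for each, the SCC9 hairpins were not tested against each other alone, and limma called neither miRNA for the hairpins over both lines.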
